A study of Mus musculus with 16 samples.

How the data were processed

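The series holds 16 one-colour arrays of total RNA labelled with Cy3, from whole liver and from hepatic inflammatory cells of female C57Bl/6 mice. The mice had eaten an atherogenic high-fat diet for 40 weeks, per the labels, and were then treated with phosphate-buffered saline (PBS) or with adipose tissue-derived stem cells (ADSC). The cells were grown from the inguinal fat of mice carrying a GFP transgene. They were given in 2 injections of 100000 cells each under the capsule of the spleen, and tissue was taken 2 weeks after the last injection. There were 4 arrays in each of 4 groups: liver PBS, liver ADSC, inflammatory cells PBS and inflammatory cells ADSC. PBS arrays carry the numbers 11 to 14 and ADSC arrays the numbers 7 to 10 in both sample types. The labels do not say that a number stands for an animal, or that each array comes from a separate animal, so the p-values measure the spread between samples. The RNA extraction protocol in the labels names inflammatory cells infiltrating a tumor, and blood, so how the inflammatory cells were isolated is not settled by it.

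Each sample has 1 scanner text file. The processed signal used here is an intensity, per the file headers: Agilent Feature Extraction 10.5.1.1 subtracted the background and detrended the signal of each array, with no normalization between arrays. The median spot signal and the median local background, both intensities before subtraction per the file headers, served an alternative. The files' 0 or 1 marks for spots well above background, outlying spots and saturated spots were read from the same files. The deposited value table of the series is also on the linear intensity scale: set against the scanner files spot by spot, the largest relative difference was 0, so it was neither centred nor transformed. Its medians were 34.3, 74.9, 44.4 and 62.1 for liver PBS 11 to 14, 58.7, 49.4, 41.9 and 54.3 for liver ADSC 7 to 10, 61.5, 86.3, 50.9 and 97.4 for inflammatory cells PBS 11 to 14, and 65.3, 32.2, 50.6 and 51.5 for inflammatory cells ADSC 7 to 10. The file of inflammatory cells ADSC 9 holds values of 3 significant digits.

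Each array held 43379 non-control spots of 41174 probes. Spots marked as outliers, 71 to 124 per array, were left out, and 0 spots were saturated. The log2 processed signal had the array's 75th percentile over non-control probes subtracted, and the spots of a probe were averaged. Symbols were taken from the GRCm38.p6 annotation by the accession in the scanner files, which named 23374 probes with 16535 symbols, and the other 17800 probes kept the name in the file. This gave 33269 gene names, of which 6361 had several probes, and the probe with the highest mean over the 16 arrays stood for the gene. No genomic positions are given, since the array and the annotation use different builds. A gene was tested where its probe was well above background on at least 4 arrays of the fit. Where a probe was not well above background on any array of a group, the fold is a bound, written as at least. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Short probes of near-identical families, such as Chil3 and its neighbours or the trypsins Try5, Prss2 and Prss3, may pick up each other's transcripts.

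Genes were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. ADSC was set against PBS in the 8 liver arrays and in the 8 inflammatory cell arrays separately. The difference between those effects, and inflammatory cells against liver, were contrasts in 1 fit of all 16 arrays with 4 group means. Log2 fold changes are given with the standard error (SE) of the fit, and group means with the standard deviation (SD). The 36 gene lists covered liver functions, matrix and fibrosis, lipid and bile acid metabolism, inflammation, stress and cell types, exocrine pancreas and red cells included, and a Y-linked list that served only to check the sex label. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The same lists were tested with camera at an estimated correlation, with limma's fry, which asks whether a list moves on balance in 1 direction, and with an exact two-sided permutation test of the list means. For the difference between sample types, that permutation test took the inflammatory cell mean minus the liver mean of the same number. With 4 arrays against 4, the smallest exact p is 0.0286. Members were also counted at a p adjusted over the list alone.

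Genes to be named were set by a rule for each comparison. They were the 10 largest rises and 10 largest falls among passing genes with a symbol (filled up to 5 by the smallest p where fewer passed), the 3 members with the smallest p of each called list, 21 genes of liver function, fibrosis and immune cells whatever their values, and the 5 genes with the smallest p for the difference between sample types. Of the 21 genes, Cd8a, Ly6g and Mki67 had no probe with that symbol. The groups, the comparisons, their tests, the gene lists, this rule and the first alternatives below were chosen before the data were examined.

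The first alternatives were other normalizations (quantile, the 75th percentile over probes well above background on all arrays, and normexp background correction with an offset of 50 before either scaling), other filters on dim probes, every probe or the mean of a gene's probes, trend and robust in eBayes, array weights, slide as a fixed or random block, all 16 arrays in 1 fit, the shared number as a block, leaving out each array, other thresholds, and the value table itself. Scan day, array brightness, the exocrine pancreas list mean, leaving out the 3 arrays richest in pancreas transcripts, and array weights by the gene by gene method were added after the data were seen. The arrays lay on 5 slides scanned on 3 days, numbered here in order. Liver arrays were at positions 1 and 2 of the slides and inflammatory cell arrays at positions 3 and 4.

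The scripts were tested on simulated data drawn from the real means and spreads, with 100 genes changed by 1 and 100 by 2 on the log2 scale. In the liver fit 62 and 95 were recovered, in the inflammatory cells 14 and 78, in the difference 11 and 59, and in the contrast of sample types 70 and 92. With the neutrophil list also shifted by 2, 4.82%, 0.99%, 11.25% and 7.98% of the calls were false, in the same order. The changed genes were drawn at random. In liver the neutrophil genes had a median SD of 1.17 against 0.25 over all genes, so this recovery does not hold for them. A shift of 1 on the log2 scale given to the neutrophil list was missed by camera in the simulated liver (adjusted p = 0.742) and a shift of 2 was found (adjusted p = 4e-09). Genes were drawn independently, so the simulation says nothing about correlation within a list. Coverage of a sample by the array is limited by signal over background: 51.6% to 66.4% of spots were well above background, and the number of arrays limits the precision.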

Results

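Gene expression was measured on 16 arrays, 1 per RNA sample, in mice with cirrhosis after 40 weeks of an atherogenic high-fat diet. The samples were whole liver and hepatic inflammatory cells, a cell fraction taken from the liver, each from mice given PBS or adipose tissue-derived stem cells (ADSC), a type of mesenchymal cell grown from fat. Each of the 4 groups held 4 arrays. Between 51.6% (liver PBS 11) and 66.4% (inflammatory cells ADSC 7) of spots were well above background. The 75th percentile of the processed signal ran from 123.8 (inflammatory cells ADSC 8) to 551.9 (liver PBS 12). Within groups, correlations between arrays lay between 0.960 and 0.976 for liver PBS, 0.978 and 0.984 for liver ADSC, 0.932 and 0.972 for inflammatory cells PBS, and 0.921 and 0.968 for inflammatory cells ADSC. All levels below are log2 signal relative to the array's 75th percentile.

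Inflammatory cells were first set against whole liver, to describe what the isolated fraction held. Lymphocyte genes stood far above their level in liver: all 21 measured T cell genes, all 18 cytotoxic and NK cell genes and 15 of 17 B and plasma cell genes were higher, with list medians of 3.88, 3.87 and 4.43. Higher too were 18 of 19 neutrophil genes (median 3.23), 14 of 16 dendritic cell genes (2.43), all 9 MHC class II genes (1.28), 15 of 22 cytokines and chemokines (3.62) and all 10 erythroid genes (3.89). Hepatocyte transcripts were lower: all 23 hepatocyte function genes (median -5.40), 17 of 18 genes of xenobiotic metabolism (-5.26), 19 of 20 acute phase genes (-5.26) and 14 of 15 genes of bile acid synthesis and transport (-5.12). Collagen and matrix genes were lower for 23 of 24 members (-3.41). Each of these counts was the same when adjusted over the list alone. Macrophage genes went both ways: of 19 monocyte and macrophage genes 9 were higher and 3 lower (median 0.04, with 9 and 2 adjusted over the list alone), and of 11 Kupffer cell genes 5 were higher and 3 lower (0.06, with 4 and 3).

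The largest differences named single functions. Hspa1b and Hspa1a, inducible heat shock proteins, were higher in inflammatory cells by 9.86 ± 0.31 and 9.57 ± 0.24 on the log2 scale (SE, 8 arrays against 8), as were Cxcl2, a neutrophil-attracting chemokine, by 8.62 ± 0.39 and Ifng, which encodes interferon gamma, by 8.46 ± 0.25. All 18 immediate early and stress genes were higher (median 4.51). Liver-enriched enzymes and transporters were lower: Bhmt2 by -8.50 ± 0.36, Abcg5, a sterol transporter, by -7.97 ± 0.37, Saa2, an acute phase protein, by -7.96 ± 0.41, Ftcd by -7.95 ± 0.29, Baat, which conjugates bile acids, by -7.89 ± 0.48, Gys2, the liver glycogen synthase, by -7.81 ± 0.40, Gckr, the glucokinase regulator, by -7.73 ± 0.24 and Sgk2 by -7.71 ± 0.31. With normexp background correction Baat, Sgk2 and Bhmt2 moved to -5.00, -4.78 and -5.70 and Cxcl2 to 6.19, all still passing, so sizes of genes dim in 1 sample type depended on it. Dmgdh and Cyp4f15 were not well above background on any inflammatory cell array and were at least 137-fold and at least 92.1-fold lower there. Digestive enzymes of the exocrine pancreas were the other extreme: Cela3b, Prss3, Cpa1, Try5, Prss2 and Cpb1 were not well above background on any liver array and were at least 315-fold, 274-fold, 267-fold, 209-fold, 155-fold and 132-fold higher in inflammatory cells. All 10 measured members of the exocrine pancreas list were higher (median 8.29). In total 18655 of 22145 genes passed in limma, 10860 higher and 7795 lower in inflammatory cells, and the median over all genes was 0.36. That median depended on the scaling, from 0.13 with normexp and quantile normalization to 0.68 with the 75th percentile over detected probes, so these differences are relative to it. With the 75th percentile over detected probes 12285 were higher and 6404 lower. Among probes above background on every array 4861 were higher and 5578 lower.

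The pancreas transcripts were uneven among the inflammatory cell arrays. The mean of the 10 list members was 6.29 in PBS 11, 8.28 in PBS 13 and 8.48 in ADSC 10, between -1.55 and 2.31 in the other 5 arrays, and between -4.89 and -3.89 in the livers.

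**Figure D1:**
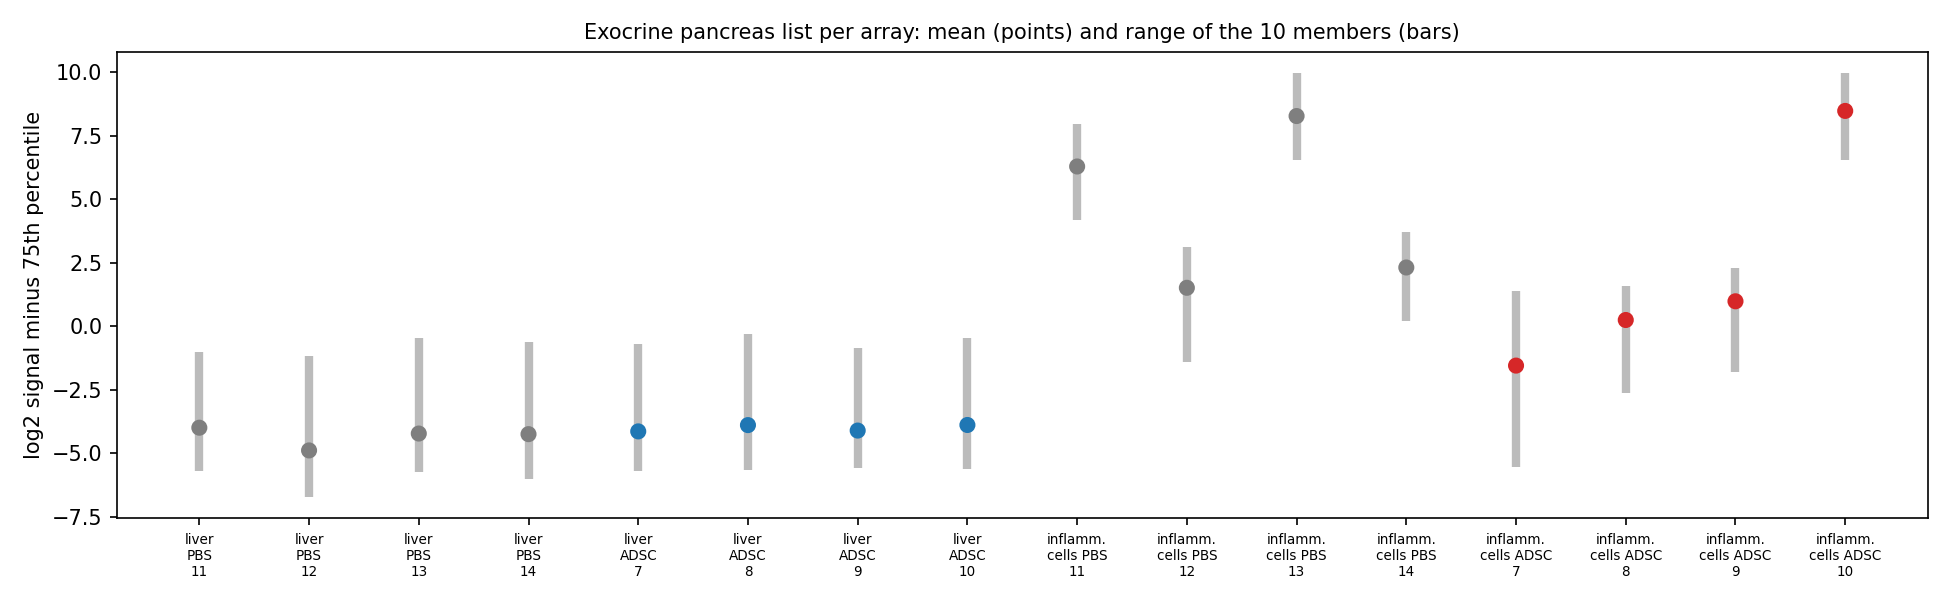
Exocrine pancreas transcripts on each array. Points give the mean of 10 list members in log2 signal minus the array's 75th percentile, and bars the range of the members. Inflammatory cells PBS 11, PBS 13 and ADSC 10 had means of 6.29, 8.28 and 8.48, while the livers lay between -4.89 and -3.89.

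In the inflammatory cells, the question was which genes differed after ADSC treatment. Neutrophil granule genes fell the most. Of 19 measured neutrophil genes, 16 fell over all genes tested and 19 when adjusted over the list alone, and the list mean was 4.35 ± 0.88 (SD, n = 4) in PBS and 1.02 ± 0.32 (SD, n = 4) in ADSC, with every ADSC array below every PBS array. Examples were Elane, neutrophil elastase (probe A_51_P144551, 26.0-fold lower, log2 -4.70 ± 0.61 SE, adjusted p = 0.00764), Ctsg, cathepsin G (A_51_P416546, 23.3-fold lower, adjusted p = 0.00242), Ltf, lactoferrin (A_52_P15388, 21.7-fold lower, adjusted p = 0.00262), and Mpo, myeloperoxidase (A_51_P317460, 18.2-fold lower, adjusted p = 0.0102). Ngp, Camp, Lcn2 and Itgb2l of the same list fell by 4.37, 4.34, 4.14 and 4.09 on the log2 scale. Outside the list, Cxcl5, a neutrophil-attracting chemokine, dropped by 4.37 and Wfdc21 fell by 4.03. In each gene named in this paragraph, all 4 ADSC arrays lay below all 4 PBS arrays, which chance gives for 2.86% of genes in either direction. These genes were picked for their large falls, so the separation of their arrays adds no evidence. With normexp background correction the value of Elane moved to -2.46 and that of Cxcl5 to -1.75, both still passing, so the sizes depended on how background was treated.

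Monocyte and macrophage genes were also lower, with 19 of 19 estimates negative (median -0.97). Of these, 5 fell over all genes and 17 when adjusted over the list alone, Ly6c1 by 2.47, Cd14, a receptor for bacterial lipopolysaccharide, by 1.99 and Fcgr3, an IgG receptor, by 1.74 among them. Members such as Cd14 and Fcgr3 are not limited to macrophages, so this fall was not separated from that of neutrophil genes. Of 11 Kupffer cell genes (resident liver macrophages, median -1.16), 2 fell over all genes and 8 over the list alone: the 2 were Slc40a1, the iron exporter, by 1.59 and Cd5l by 1.70, while Vsig4 was at -2.29 (adjusted p = 0.0635). Among 21 cytokines and chemokines (median -0.63), 1 fell over all genes and 8 over the list alone. That 1 was Il1b, an inflammatory cytokine (3.81-fold lower, adjusted p = 0.0255), with Osm at -1.81 (adjusted p = 0.0504) and Cxcl2 at -1.54 (adjusted p = 0.0709). Of 26 cell cycle genes (median -0.63), 1 fell over all genes and 6 over the list alone. It was Cdk1, the mitotic kinase, 3.63-fold lower (adjusted p = 0.019), with Bub1 at -1.51 and Tyms at -1.14, and Cdk1 moved to -0.58 and no longer passed with the mean of its probes, nor did it with normexp background correction before the 75th percentile. Of 20 interferon response genes (median -0.51), 2 fell over all genes and 5 over the list alone: Rtp4 by 1.12 and Oas1a by 1.01, with Ifit2 at -0.90. The 1 passing member of the matrix remodelling list (6 over the list alone, median -0.29) was Mmp8, a neutrophil collagenase, and Mmp9 and Mmp12 were at -2.91 and -0.98. Both Mmp8 and Mmp9 are also in the neutrophil list. The 19 genes of oxidative phosphorylation had a median of -0.45 with 0 passing either way, and Sdhb, Ndufb8 and Cox5a were at -0.63, -0.52 and -0.51.

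B cell and antigen presentation genes lay on the other side. The median was 0.99 over 17 B and plasma cell genes and 0.62 over 9 MHC class II genes. None passed over all genes, and 10 and 5 passed as higher when adjusted over the list alone. Cd22 and Fcer2a, B cell surface receptors, were at 1.88 ± 0.44 and 1.58 ± 0.34 (SE, adjusted p = 0.0709 and 0.0584), Tnfrsf13c at 1.45 and Ciita, the regulator of MHC class II genes, at 1.39. H2-DMb2 and H2-Ob were at 1.24 and 1.21. Hepatocyte function genes had a median of 0.64 over 20 members with 0 passing either way, with Apoa1, Serpinc1 and F2 at 1.58, 1.45 and 1.24. Genes of xenobiotic metabolism had a median of 0.62 over 16 members, with 0 passing over all genes and 2 over the list alone, and Cyp2a5, Cyp2f2 and Ugt2b5 at 1.59, 1.51 and 1.35. The exocrine pancreas list had a median of -2.63 with 0 of 10 members passing either way, and Cela2a, Cpb1 and Cela3b were at -3.47 ± 2.40, -3.35 ± 2.29 and -3.06 ± 2.19 (SE). The list means were 6.29, 1.51, 8.28 and 2.31 in PBS 11 to 14 and -1.55, 0.24, 0.98 and 8.48 in ADSC 7 to 10. Genes that rose included Svs2 (at least 2.27-fold, since it was not well above background on any PBS array), Sostdc1 (4.19-fold), Chst3 (3.25-fold), Dclk2 (2.84-fold), Scd1, a fatty acid desaturase (2.67-fold), Mef2c (2.58-fold), Ablim1 (2.58-fold), Srpk3 (2.57-fold) and Zfp318 (2.51-fold). With normexp background correction and quantile normalization Sostdc1, Svs2 and Ablim1 did not pass (log2 0.52, 0.57 and 0.77), and Dclk2 passed at 0.95.

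Of the genes chosen for liver and immune function, the T cell genes Cd3e and Cd4 were at -0.19 and 0.22, Adgre1 and Itgam of the monocyte and macrophage list at -1.14 and -0.97, Ccl2 at -1.32, Il10 at -0.59, Hgf at -0.57, Il6 at -0.47 and Tnf at -0.38. Col1a1, Alb, Col3a1, Tgfb1, Timp1 and Acta2 were at 0.69, 0.70, 0.38, 0.22, 0.16 and -0.27. None of these 15 passed. The Tgfb1 value depended on PBS 13, where it was at -0.12 against 1.42 to 1.66 in the other PBS arrays.

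**Figure D2:**
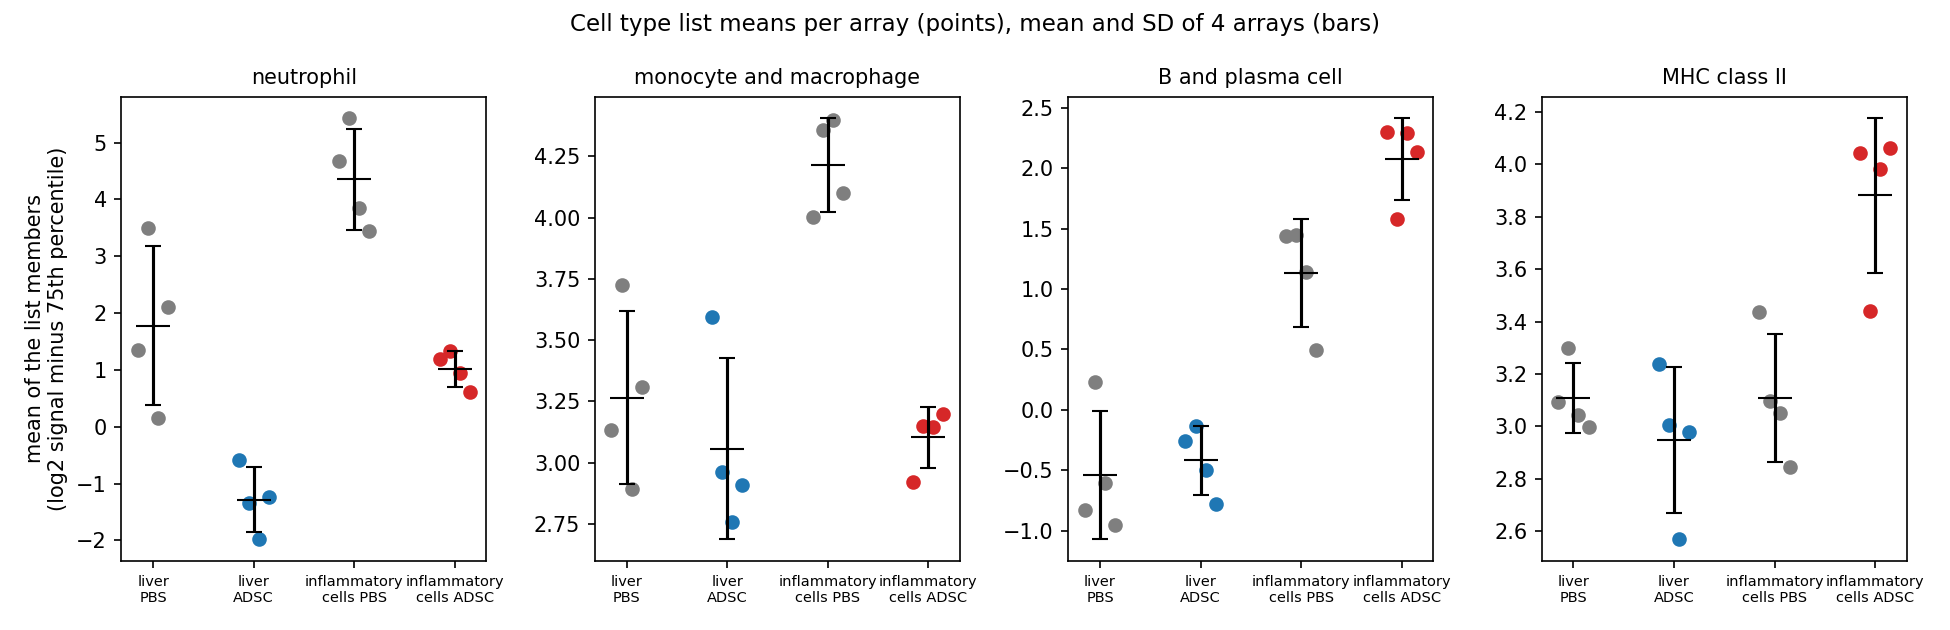
Means of the neutrophil, monocyte and macrophage, B and plasma cell, and MHC class II lists on each array, in log2 signal minus the array's 75th percentile. Points are arrays, bars the mean and SD of 4 arrays. The neutrophil mean of inflammatory cells was 4.35 in PBS and 1.02 in ADSC, and that of liver 1.78 and -1.29.

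Over all 20167 genes tested, 246 passed in limma, 27 higher and 219 lower after ADSC, and 3736 had an unadjusted p under 0.05. If genes were independent chance would give 1008, but 2 other splits of the 8 arrays into 4 and 4, of 35 with the real one, reached 3736 as well, with 4597 the highest. Without PBS 12, ADSC 8 or ADSC 9 the number at an unadjusted p under 0.05 was 2283, 2428 or 2455. Camera with the preset correlation called 13 of 35 lists, 4 higher and 9 lower, with adjusted p = 5.25e-31 for the neutrophil list, 4.51e-15 for monocytes and macrophages, 3.08e-07 for the cell cycle, 1.12e-06 for B and plasma cells, 3.46e-06 for cytokines, 2.4e-05 for Kupffer cells, 0.000113 for oxidative phosphorylation, 0.000165 for MHC class II, 0.000179 for the interferon response, 0.00994 for hepatocyte function and xenobiotic metabolism, 0.0182 for matrix remodelling and 0.03 for the pancreas. With an estimated correlation 0 lists passed: the adjusted p was 0.143 for monocytes and macrophages, 0.192 for neutrophils, 0.382 for B and plasma cells, cytokines, Kupffer cells, MHC class II, interferon response and matrix remodelling, 0.449 for the cell cycle, 0.482 for oxidative phosphorylation, 0.625 for xenobiotic metabolism, 0.709 for hepatocyte function and 0.744 for the pancreas. Fry called 2, the monocyte and macrophage list (adjusted p = 0.00263) and the neutrophil list (adjusted p = 0.0054). The exact permutation test of list means gave p = 0.0286, the smallest possible, for 9 lists, and an adjusted p of 0.111 for each. Within scan days and slides that held both treatments, the neutrophil median was -4.03 on day 2, -3.56 on day 3, -3.56 on slide 2 and -4.51 on slide 3, and the mean was -3.51 with scan day as a term and -3.08 with slide as a block.

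The number of genes depended on single arrays: it was 71 without ADSC 9 (2 higher and 69 lower), 80 without PBS 12 (2 and 78), 89 without ADSC 10 (3 and 86), 138 without ADSC 8 (17 and 121), 504 without ADSC 7 (196 and 308), and 0 of 18769 in limma (4596 at unadjusted p under 0.05) without the 3 pancreas-rich arrays, where the neutrophil mean was -3.21. With all 8 arrays it ran from 61 with array brightness as a covariate to 5147 with array weights, and 12 of the 35 splits, the real one included, called at least 13 lists. The share of lower genes moved too, with 354 higher and 450 lower with slide as a fixed block and 3044 higher and 2103 lower with array weights. Camera lost the pancreas list without PBS 11, PBS 13, ADSC 7, ADSC 8 or ADSC 9 (medians -2.01, -1.49, -1.42, -2.09 and -2.28, and -4.81 without ADSC 10), matrix remodelling without PBS 11 or ADSC 7 (-0.27 and -0.19), hepatocyte function without PBS 13 or ADSC 8 (0.66 and 0.36) and xenobiotic metabolism without ADSC 8 (0.41), and the cell cycle median was -0.39 without PBS 12. The matrix remodelling median turned to 0.00857 with no filter on dim probes and to 0.000387 with slide as a fixed block. Scaling to the 75th percentile over detected probes moved the median of all genes from 0.03 to 0.15, and the changes are relative to it.

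In whole liver, where the question was again which genes differed after ADSC, neutrophil genes had the largest median shift of the 34 lists tested (-3.03). The mean of 16 measured members was 1.78 ± 1.40 (SD, n = 4) in PBS and -1.29 ± 0.57 (SD, n = 4) in ADSC, with every ADSC array below every PBS array. None of the 16 passed over all genes, and 15 passed as lower when adjusted over the list alone. Ngp was at -4.46 ± 0.77, S100a9, a calprotectin subunit, at -3.18 ± 0.59 and Lcn2 at -1.92 ± 0.35 (SE, adjusted p = 0.514, 0.562 and 0.562). Lcn2 was the 1 gene of the list that was lower in inflammatory cells than in liver (-1.40). Its fall in liver need therefore not be one of neutrophils. Acute phase genes, which hepatocytes make in inflammation, had a median of -0.36 over 20 members, with 0 passing over all genes and 4 lower over the list alone, among them Itih3 (-0.58 ± 0.09), Orm1 (-0.78 ± 0.16) and Orm3 (-1.19 ± 0.24).

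Other inflammatory lists lay lower by smaller amounts. Cytokines and chemokines had a median of -0.36 over 16 members (0 over all genes, 1 lower over the list alone), with Cxcl1, a neutrophil-attracting chemokine, at -1.35, Il1b at -1.48 and Tnf at -1.19. The interferon response (median -0.32 over 20 members, 0 passing either way) included Ifit1, Irf7 and Oas2 at -0.47, -0.44 and -0.38. Alternatively activated macrophage genes (-0.29 over 8, with 0 over all genes and 1 lower alone) included Chil3 at -2.19, Mrc1 at -0.37 and Il4ra at -0.30. Kupffer cell genes had a median of -0.51 over 9, with Marco at -1.24, Clec4f at -1.06 and C6 at -0.51, and monocyte and macrophage genes -0.15 over 19, with Cd14 at -1.38, Ly6c1 at -1.20 and Itgam at -0.78. Platelet genes (-0.35 over 6) included Ppbp at -1.55, Treml1 at -0.52 and Pf4 at -0.42, MHC class II genes (-0.17 over 7) Cd74, H2-DMb1 and H2-Ab1 at -0.31, -0.26 and -0.22, and immediate early genes (-0.12 over 17) Ier3, Jund and Jun at -1.03, -0.28 and -0.28. In these 5 lists 0 members passed either way. Of 6 erythroid genes (-0.34) 0 passed over all genes, and 2 lower and 1 higher over the list alone, with Slc4a1 at -1.39, Hba-a1 at -0.56 and Bpgm at -0.34. The calls of several of these lists were lost without 1 array. Where the median stayed as large, as for MHC class II without PBS 11 or PBS 13, a lost call with fewer arrays does not show that the list rested on that array. Camera lost Kupffer cells without PBS 14 or ADSC 8 (medians -0.19 and -0.28), platelets without PBS 14 (-0.29, and -0.22 without ADSC 8), immediate early genes without PBS 12 (-0.10), MHC class II without PBS 11, PBS 12, PBS 13 or ADSC 9 (-0.22, -0.0715, -0.20 and 0.0137), and monocytes and macrophages without PBS 12, ADSC 8, ADSC 9 or ADSC 10 (-0.00816, -0.11, -0.0657 and -0.0897). Other medians moved by over 1.5 times with the call unchanged: immediate early genes to -0.21, -0.23 and -0.18 without PBS 11, PBS 13 and ADSC 9, monocytes and macrophages to -0.27, -0.30, -0.0914 and -0.34 without PBS 11, PBS 13, PBS 14 and ADSC 7, and the interferon response and MHC class II to -0.53 and -0.31 without ADSC 7.

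Genes of matrix, lipid synthesis and proliferation lay slightly higher in the liver after ADSC, with 0 members passing either way. Collagen and extracellular matrix genes had a median of 0.22 over 23 members, with Sparc, Lum and Dcn at 0.38, 0.34 and 0.32. Stellate cell and myofibroblast genes, from the cells that make scar collagen, had a median of 0.14 over 16, with Reln, Lrat and Tpm2 at 0.65, 0.58 and 0.36. Fatty acid synthesis genes had a median of 0.42 over 16, with Fads1, Scd1 and Mlxipl at 0.53, 0.49 and 0.40. Xenobiotic metabolism genes had a median of 0.25 over 18, with Gstt1, Ugt2b5 and Cyp2c29 at 0.62, 0.49 and 0.45. Cell cycle genes had a median of 0.15 over 22, with Ccnb2, Cdc20 and Foxm1 at 0.52, 0.44 and 0.39. The calls of these lists too were lost without 1 array. The medians of collagen without PBS 13 and of stellate cells without PBS 11 or PBS 13 were no smaller. Those lost calls do not show that the lists rested on these arrays. Camera lost collagen without PBS 13 or ADSC 7 (medians 0.27 and 0.0734), stellate cells without PBS 11, PBS 13, ADSC 7 or ADSC 8 (0.16, 0.16, 0.0523 and 0.0821), fatty acid synthesis without PBS 12, PBS 14 or ADSC 10 (0.17, 0.35 and 0.28), the cell cycle without PBS 13 or ADSC 7 (0.0714 and 0.11), and xenobiotic metabolism without PBS 12, ADSC 9 or ADSC 10 (-0.00285, 0.16 and 0.21). With the call unchanged, collagen moved to 0.14 and 0.36 without PBS 12 and ADSC 9, stellate cells to 0.22 and 0.22 without ADSC 9 and ADSC 10, fatty acid synthesis to 0.66 without PBS 13, the cell cycle to 0.29 without PBS 12, and xenobiotic metabolism to 0.42, 0.39 and 0.47 without PBS 11, PBS 13 and ADSC 7. The hepatocyte genes Alb, Hnf4a and Cyp7a1 were at 0.05 ± 0.18, 0.00 ± 0.23 and 0.27 ± 1.08 (SE), and the fibrosis genes Col1a1, Col3a1, Acta2, Timp1 and Tgfb1 at 0.28 ± 0.25, 0.26 ± 0.29, -0.04 ± 0.15, -0.02 ± 0.24 and -0.07 ± 0.16. Ccl2, Adgre1, Cd3e and Hgf were at -0.35, -0.20, 0.28 and 0.12.

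Limma passed 0 of 17321 genes in the liver. At an unadjusted p under 0.05 there were 806, which 11 of the 35 splits of the 8 arrays, the real one included, reached (highest other 3308). This number was 1342 without PBS 13 and 471 without ADSC 8. With all 8 arrays the smallest adjusted p was 0.271. The genes with the smallest p, none passing, were Nnmt (-1.38), Gda (-0.77), Il20rb (-1.01), Amer2 (at least 1.90-fold lower) and Trem1, a receptor of neutrophils and monocytes (at least 4.16-fold lower), and on the higher side Krt20 (1.99), Ddit4l (0.61), Pla2g5 (1.32), Cdk5r2 (0.65) and Zfp738 (0.76). Camera with the preset correlation called 16 of 34 lists, those described above, 5 higher and 11 lower, with adjusted p from 4.78e-33 for neutrophils and 2.27e-13 for the acute phase to 0.0279 for MHC class II. With an estimated correlation 0 lists passed: the adjusted p was 0.119 for neutrophils, acute phase and cytokines, 0.14 for alternatively activated macrophages, 0.208 for erythroid genes, 0.369 for interferon and immediate early genes, 0.525 for platelets, 0.601 for the cell cycle, Kupffer cells, stellate cells and MHC class II, 0.779 for collagen, 0.805 for fatty acid synthesis and 0.814 for xenobiotic metabolism and for monocytes and macrophages. Fry called 0 lists (smallest adjusted p = 0.0974). The exact permutation test gave p = 0.0286 for the neutrophil and acute phase lists, and 0.389 after adjustment.

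Scan day and treatment were largely shared in the liver: day 1 held only ADSC arrays (8 and 10), day 3 only PBS arrays (11, 12 and 14), and day 2 PBS 13 with ADSC 7 and 9. The neutrophil median was -1.60 within day 2 and -0.78 within slide 2 (1 array against 1), and the mean was -1.44 with scan day as a term and -2.55 with slide as a block. Since days 1 and 3 held 1 treatment each, the fit with scan day as a term compares only PBS 13 with ADSC 7 and 9. Its values are those within day 2 and rest on 1 PBS array. With scan day as a term the median changed sign for immediate early genes (0.0948), Kupffer cells (0.29), monocytes and macrophages (0.30), platelets (0.23), cytokines (0.0150), the interferon response (0.00487) and xenobiotic metabolism (-0.26), the last also without liver PBS 12 (-0.00285). Fatty acid synthesis then lay in the opposite direction (-0.57). Its adjusted p by camera or fry ran from 2.26e-05 to 0.805 over all alternatives. With slide as a fixed block in the fit of all 16 arrays the median changed sign for erythroid genes (0.31), monocytes and macrophages (0.26), platelets (0.25), alternatively activated macrophages (0.13), MHC class II (0.0653) and the interferon response (0.00543), and camera's direction for cytokines (-0.0297) and fatty acid synthesis (0.0786), whose medians kept their sign. Array weights called 3040 genes in the liver in a fit that did not converge, gene by gene weights 13, 1 fit of all 16 arrays 9 and the mean of a gene's probes 1, and 10 of the 35 splits of the arrays, the real one included, called at least 16 lists.

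**Figure D3:**
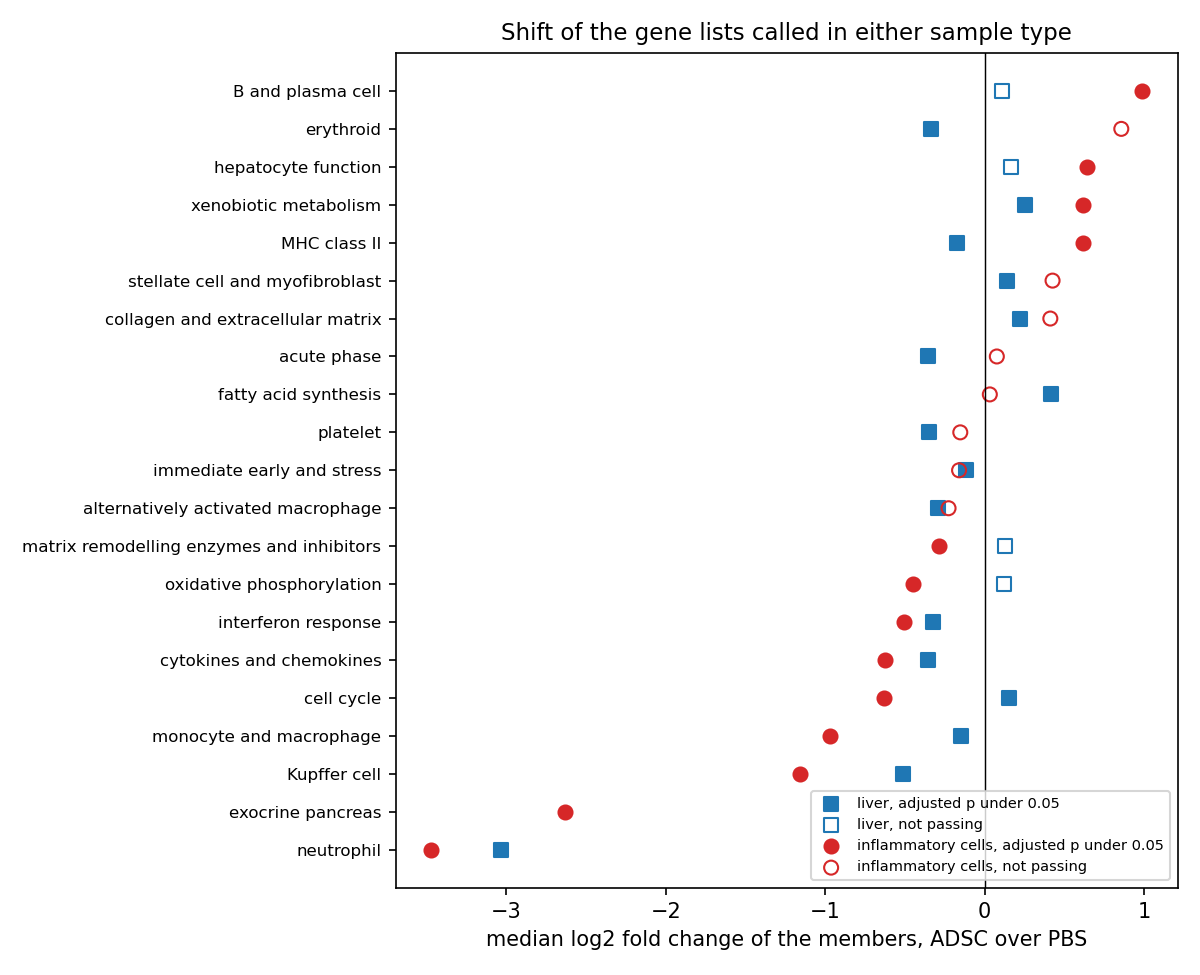
Median log2 fold change of the members, ADSC over PBS, for each gene list that camera called in liver or inflammatory cells. Squares are liver and circles inflammatory cells, filled where the adjusted p at the preset correlation was under 0.05. The neutrophil medians were -3.03 in liver and -3.47 in inflammatory cells.

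The treatment effects of both sample types were then tested against each other. The neutrophil shift was not shown to differ between them (median difference -0.26, adjusted p = 0.729). In cell cycle genes the effect in inflammatory cells was the lower by a median of -0.90 over 27 members, with 1 passing over all genes and 11 over the list alone, and in monocyte and macrophage genes by -0.94 over 19, with 0 and 7. MHC class II genes (0.80 over 9) had 0 and 5 members with the higher effect in inflammatory cells, and Kupffer cell genes (-0.90 over 11) 0 and 2 with the lower. In B and plasma cell (0.81 over 17), erythroid (1.00 over 10), hepatocyte function (0.49 over 23), oxidative phosphorylation (-0.59 over 19) and exocrine pancreas genes (-2.78 over 10) 0 members passed either way.

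Of 22145 genes 7 passed in limma, all with the lower effect in inflammatory cells, and 2236 had an unadjusted p under 0.05, a number that 9 of 100 splits, the real one included, reached. With number, slide, both, or scan day as terms 0 passed (2043, 2141, 2229 and 2108 at an unadjusted p under 0.05). By the rule these were Mfsd7a (-2.04 ± 0.28), Prdx5, a peroxiredoxin (-1.76 ± 0.25), Ppp1r42 (-3.92 ± 0.59), Smim5 (-1.96 ± 0.30) and Dstn, an actin-depolymerising protein (-2.11 ± 0.33, SE). The others, BC049694 (-2.76 ± 0.36) and Cdk1 (-2.35 ± 0.38), were chosen after their values were seen, since so few passed. Mfsd7a and Ppp1r42 were not well above background on any inflammatory cell array after ADSC, so their values are not sizes of an effect. With normexp background correction before the 75th percentile they moved to -0.51 and -1.23 and did not pass, and Smim5 moved to -1.20 and passed. Camera called 9 of 35 lists, the 9 just given, with adjusted p from 1.08e-09 (cell cycle) to 0.0454 (pancreas). With an estimated correlation 0 passed: the adjusted p was 0.516 for MHC class II and for monocytes and macrophages, 0.652 for the cell cycle, 0.654 for B and plasma cells and 0.923 for the other 5. Fry called 0 (smallest adjusted p = 0.0978), and the exact permutation test gave a smallest adjusted p of 0.333.

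The number of genes was 0 without liver PBS 12, 13 or 14, without liver ADSC 7, 8 or 10 and without the 3 pancreas-rich arrays (3479 at unadjusted p under 0.05), 1 without inflammatory cells ADSC 10, 2 without liver PBS 11 or inflammatory cells PBS 13, 3 without liver ADSC 9 or inflammatory cells ADSC 9, 4 without inflammatory cells ADSC 8, and 14, 20 and 46 without inflammatory cells PBS 11, ADSC 7 and PBS 14. The number of lists was 5 without liver PBS 11 or 13, and 78 of 100 splits called at least 9. Camera lost the pancreas list without liver PBS 11 to 14, ADSC 8 or ADSC 10 (medians -3.18, -2.57, -2.77, -2.96, -2.74 and -2.71) or inflammatory cells PBS 11, PBS 13, ADSC 7, ADSC 8 or ADSC 9 (-2.23, -1.55, -1.61, -2.22 and -2.41). It lost hepatocyte function without liver PBS 11, PBS 13 or ADSC 7 (0.43, 0.39 and 0.30) or inflammatory cells PBS 11, PBS 13, PBS 14 or ADSC 8 (0.48, 0.60, 0.40 and 0.19), erythroid genes without liver PBS 11 or PBS 13 (1.00 and 0.75) or inflammatory cells PBS 13, ADSC 8, ADSC 9 or ADSC 10 (0.74, 0.75, 0.56 and 0.78), and Kupffer cells without liver PBS 11 or PBS 13 or inflammatory cells ADSC 7 (-0.86, -0.76 and -0.74). With the call unchanged, hepatocyte function moved to 0.75 without liver PBS 12, and without inflammatory cells PBS 12 the cell cycle and Kupffer cells moved to -0.59 and -0.52, without PBS 14 B and plasma cells to 0.50, without ADSC 7 erythroid genes to 1.73 and without ADSC 10 the pancreas to -4.89.

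Across the 15725 genes tested in both sample types, the log2 fold changes had a Pearson r of 0.324 and a Spearman rho of 0.210, genes not being independent replicates. Of the 219 genes that fell in inflammatory cells 187 were tested in the liver, and 145 of these had a negative estimate there (median -0.32), 56 at an unadjusted p under 0.05. Of all genes tested in both, 40.6% had a negative estimate in the liver.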

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

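The tests of the neutrophil shifts by scan day, slide, single array and brightness were chosen only after the results were seen. So was the test of pancreas transcripts in the livers. The tests on other splits of the arrays were set beforehand. The test on further pancreas genes was set before its result was seen, on arrays picked by their pancreas list mean.

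Among 432 groups of 4 values examined, 25 held 1 array far from the other 3. Chance gives about 5%, which is close to this share, so the values below describe the arrays and are not evidence that any array is faulty. By number of outlying spots, liver PBS 13 had 95 against 117 to 119 in the other liver PBS arrays. Liver PBS 12 stood apart in list means, at -0.30 for the cell cycle (others -0.76 to -0.71), 3.15 for fatty acid oxidation (3.53 to 3.59), 3.64 for the oxidative stress response (4.24 to 4.33) and 3.40 for xenobiotic metabolism (4.52 to 4.68), and in the genes Tpm2, at -1.01 (-0.74 to -0.71), and H2-Ab1, at 6.62 (6.14 to 6.21). Ccl2 was at 3.31 in liver PBS 13 (3.73 to 3.77 in the others). In liver ADSC 7 the bile acid list mean was 2.26 (3.02 to 3.08), Cyp2c29, a drug-metabolising enzyme, was at 5.81 (6.79 to 6.82), Ly6c1 at 0.62 (-0.83 to -0.61) and Col1a1, a fibrillar collagen, at 4.41 (3.56 to 3.61). In liver ADSC 10 the alternatively activated macrophage mean was 1.07 (0.52 to 0.61), and in liver ADSC 8 Orm1 was at 5.48 (5.29 to 5.32).

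In inflammatory cells PBS 13 the circadian clock mean was -0.83 (0.03 to 0.20) and Tgfb1 was at -0.12 (1.42 to 1.66), and in PBS 12 the fatty acid oxidation mean was 0.97 (0.57 to 0.64). Inflammatory cells ADSC 8, the dimmest array, had list means of 1.75 for the acute phase (0.85 to 0.92), 3.44 for MHC class II (3.98 to 4.06) and 0.36 for stellate cells (-0.55 to -0.39), with Chst3 at 1.28 (2.08 to 2.19) and H2-DMb2 at -0.34 (0.58 to 0.68). In ADSC 7 the erythroid mean was 0.16 (2.82 to 2.99) and Tnf was at 1.68 (3.08 to 3.14), and in ADSC 10 Il6 was at 2.67 (1.26 to 1.45).

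The treatment effects of inflammatory cells and liver differed in 7 genes: BC049694 (-2.76), Mfsd7a (-2.04), Prdx5 (-1.76), Ppp1r42 (-3.92), Smim5 (-1.96), Dstn (-2.11) and Cdk1 (-2.35), given as the effect in inflammatory cells minus that in liver on the log2 scale. Mfsd7a and Ppp1r42 were not well above background on any inflammatory cell array after ADSC, so their 2 values are not sizes of an effect, and over the alternatives they ran from -2.68 to -0.51 and from -4.44 to -1.23. Prdx5 was at 4.08 and 4.09 in liver after PBS and ADSC and at 5.25 and 3.50 in inflammatory cells. By list median they differed for monocytes and macrophages (-0.94), Kupffer cells (-0.90), the cell cycle (-0.90), oxidative phosphorylation (-0.59), the exocrine pancreas (-2.78), erythroid genes (1.00), B and plasma cells (0.81), MHC class II (0.80) and hepatocyte function (0.49), as called by camera at the preset correlation. With an estimated correlation 0 of these 9 passed (adjusted p = 0.516 to 0.923), and fry called 0. Chance could not be excluded for the 7 genes, which 5 of 100 splits matched (highest other split 277), or for the 9 lists, which 78 of 100 matched (highest other 21), the real split included in both. What set the split with 277 genes apart was not traced.

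Neutrophil genes were lower after ADSC in inflammatory cells. The mean of the list shifted by -2.97 or further without any 1 array, and its median was -3.56 or lower within every scan day and slide that held both treatments, which argues against a single array and against scan day or slide as the whole cause. With array brightness as a covariate the mean was -3.37. Of the 35 splits only the real one reached the 246 genes passing (highest other 147), the smallest share that 35 splits allow. This share was not adjusted over the other split tests. Chance could not be excluded for the 3736 genes at an unadjusted p under 0.05, which 3 splits reached (highest other 4597). Nor could it for the 13 lists, which 12 reached (highest other 19), the real split included in each. The list passed fry (adjusted p = 0.0054), with an adjusted p = 0.192 with an estimated correlation. The falls were uneven across the neutrophil list. Elane lay at 0.06 to 2.87 in PBS and -4.76 to -2.82 in ADSC, and S100a9 at 9.53 to 10.57 and 8.34 to 8.91. Csf3r lay at 1.30 to 3.59 and 0.54 to 1.48, with overlap. The size of a change in neutrophil share can therefore not be read from single genes. A lower share of neutrophils in the fraction or lower expression per cell remain open, and how the cells were isolated could also matter.

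The neutrophil list was also called lower after ADSC in the liver by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.119), by fry (0.0974) or by exact permutation (0.389), and 0 of 16 members passed over all genes. The mean shifted by -2.52 or further without any 1 array, which argues against a single array. Within day 2 the median was -1.60 and within slide 2 it was -0.78, each with 1 PBS array. The mean was -1.44 with scan day as a term, a fit that rests on the same arrays of day 2. How much of the shift belongs to scan day or slide cannot be told apart from treatment, since 2 of the 3 days held 1 treatment only. Chance could not be excluded for the 16 lists, which 10 of 35 splits, the real one included, matched (highest other 23). The number of genes passing decides nothing here, since all 35 splits must give at least the real 0 (highest other 1). A batch and an effect of the treatment both remain open, and the second may be shared with the inflammatory cells.

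Exocrine pancreas transcripts stood high on 3 inflammatory cell arrays. Of 15 further pancreas genes outside the list, at least 93.3% lay above their own median in each of these, against 73.3% in PBS 14 and 20% or less in the others. The 3 arrays were picked by the list mean, and genes of the same tissue would move with it, so this outcome was close to fixed. It shows that the signal was not confined to the list, and RNA of pancreas tissue in the sample is a candidate source. Of the further genes, Sycn was at 7.39, 9.81 and 9.73 and Amy2a5, pancreatic amylase, at 6.85, 9.61 and 9.02 in PBS 11, PBS 13 and ADSC 10. The livers of the same numbers did not stand out, as the lowest of them lay -0.33 from the highest of the other 5, which argues against pancreas RNA throughout those livers if a number is an animal. For this pattern the design gives no biological explanation to test, as both treatments were among the 3 arrays.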

How the results depend on the processing

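The tests with scan day, brightness or the pancreas mean as a term, without the 3 pancreas-rich arrays and with gene by gene array weights were chosen only after the results were seen, and the others were planned. For the HIC contrast (ADSC against PBS in hepatic inflammatory cells), the 246 genes became 3313 at an unadjusted p under 0.05 and at least 1.5-fold, 140 with the 75th percentile over detected probes, 376 with normexp and the 75th percentile, 115 with no filter, 5147 with array weights, 4510 with gene by gene weights, 804 with slide as a fixed and 819 as a random block, 915 with all 16 arrays in 1 fit and 919 with the number as a random block. They became 161 with scan day, 61 with brightness, 161 with the pancreas mean as a covariate, 0 without the 3 pancreas-rich arrays (4596 at unadjusted p under 0.05 in limma, with 5 arrays left), and 71 to 504 without 1 array: 71 without ADSC 9, 80 without PBS 12, 89 without ADSC 10, 138 without ADSC 8 and 504 without ADSC 7. Leaving out the other sets of 2 PBS and 1 ADSC arrays gave 0 in 5 of 23 and a median of 52. Every set that gave 0 left out PBS 13, and sets that kept it gave 12 to 375. Yet leaving out PBS 11, PBS 13 and ADSC 7 gave 3346, so fewer arrays and the choice of arrays were not told apart. Liver genes in limma went from 0 (806 at unadjusted p under 0.05) to 312 at an unadjusted p under 0.05 and at least 1.5-fold, 1 with the mean of probes, 3040 with array weights, 13 with gene by gene weights, 9 with all arrays in 1 fit and 9 with the number as a random block, and stayed at 0 without any 1 array. With array weights 1 other split of the 35 called as many genes in liver (3987) and 1 other in inflammatory cells (8854). The 7 genes of the difference became 2081 at the unadjusted threshold, 21 with quantile normalization, 1 with the 75th percentile over detected probes, 33 and 74 with normexp before the 75th percentile and quantile, 0 with no filter, 64 for probes above background on every array, 38 with trend and robust, 2027 and 1122 with array weights and gene by gene weights, 0 with slide, number, number and slide or scan day as terms (2141, 2043, 2229 and 2108 at unadjusted p under 0.05), 0 without the 3 pancreas-rich arrays, and 0 to 46 without 1 array, 46 being without inflammatory cells PBS 14. The 18655 genes between sample types became 10439 among probes above background on every array, where fewer were tested, and 18030 to 18511 without 1 array. Of the 18655, 10328 were kept in the first case and 17991 to 18330 without 1 array. The lists called were 0 with an estimated correlation in every contrast (camera), 0, 2 and 0 by fry in liver, inflammatory cells and their difference, 9 in liver with no filter and 5 with slide fixed, and 13 to 19, 12 to 16 and 5 to 12 without 1 array. Some liver lists turned around. With slide fixed, camera's direction reversed for cytokines (median -0.0297), erythroid genes (0.31), fatty acid synthesis (0.0786), monocytes and macrophages (0.26) and platelets (0.25), and for erythroid genes in the difference (-0.0854). With scan day it reversed for fatty acid synthesis (-0.57), immediate early genes (0.0948), Kupffer cells (0.29), monocytes and macrophages (0.30), platelets (0.23) and xenobiotic metabolism (-0.26), and without liver PBS 12 for xenobiotic metabolism (-0.00285, range -0.00285 to 0.47 without 1 array). The liver fit with scan day compares only PBS 13 with ADSC 7 and 9. Except where stated, the cause was not tested. The neutrophil median stayed between -3.82 and -2.89 in inflammatory cells, called in 16 of 17 settings, and between -3.73 and -1.60 in liver, called in 14 of 16. Over all settings, the 30 passing genes that the rule named in inflammatory cells kept side and direction in 598 cases and lost the call in 198, and lists called there in 177 and 44. Lists called in liver did so in 161 and 83, with 12 reversed. Using the value table itself moved nothing. Across 8 numbers shared by liver and inflammatory cells, the correlation of the residuals ran from -0.06 to 0.17, so the main fits did not assume pairing by number. The exact permutation test of the difference did pair the list means by number. Signal over background limits what can be measured, since Hnf4a, Cyp7a1 and Foxp3 in inflammatory cells and Il6, Il10, Cd4 and Foxp3 in liver were too dim to test.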

Other observations

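The test of the B cell list against the macrophage list was chosen only after the result was seen, and the lists below were planned.

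Several liver functions were not called in whole liver. Their medians, with adjusted p by camera, were 0.16 for hepatocyte function (0.304), 0.13 for bile acids (0.459), 0.16 for fatty acid oxidation (0.0811), 0.15 for cholesterol synthesis (0.216), 0.12 for oxidative phosphorylation (0.129) and 0.04 for the oxidative stress response (0.809). Cell type lists in liver were at 0.17 for endothelial cells (0.0811), 0.16 for dendritic cells (0.101), -0.05 for T cells (0.191), 0.11 for B and plasma cells (0.29), 0.01 for cytotoxic and NK cells (0.91), -0.07 for cholangiocytes (0.604) and 0.03 for mesenchymal and adipose genes (0.416). TGF-beta signalling was at 0.01 (0.459), growth factors at 0.12 (0.809), the circadian clock at 0.05 (0.851), the unfolded protein response at 0.01 (0.883) and matrix remodelling at 0.13 (0.986).

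In inflammatory cells the medians of lists not called were 0.16 for T cells (0.547), -0.32 for cytotoxic and NK cells (0.209), -0.06 for dendritic cells (0.264), -0.23 for alternatively activated macrophages (0.103), 0.86 for erythroid genes (0.103), -0.15 for platelets (0.209), 0.08 for endothelial cells (0.73), -0.19 for cholangiocytes (0.209), 0.43 for stellate cells (0.3), 0.41 for collagen (0.209) and -0.19 for mesenchymal and adipose genes (0.0793). The acute phase list was at 0.08 (0.883), bile acids at 0.29 (0.3), fatty acid oxidation at -0.23 (0.209), fatty acid synthesis at 0.03 (0.883), cholesterol synthesis at -0.04 (0.703), immediate early genes at -0.16 (0.371), TGF-beta signalling at -0.08 (0.371), the unfolded protein response at -0.19 (0.482), the circadian clock at -0.04 (0.497), growth factors at -0.00330 (0.73) and the oxidative stress response at 0.02 (0.926). The median, the mean and camera's direction differed in sign for 8 lists in liver, 3 in inflammatory cells and 3 in the difference, none of them called.

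The Y-linked genes were at background on most arrays, with Uty above background on 1 and Eif2s3y on 3 of 16. Between inflammatory cells and liver, 18655 genes passed, and of 100 regroupings of the arrays only the real one reached this number (highest other 15661).

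A hypothesis was that a lower share of neutrophils raised the transcripts of all other cells alike in the inflammatory cells after ADSC. The B and plasma cell mean minus the monocyte and macrophage mean changed by 2.06 between treatments (exact permutation p = 0.0286, 4 arrays against 4, no overlap). On each list alone the arrays of both treatments already lay apart, in opposite directions. The lack of overlap and this p were therefore fixed beforehand and add no evidence. Both lists would have moved together under that hypothesis only if neutrophils do not express the macrophage list. Members such as Itgam, Cd14 and Fcgr3 are not limited to macrophages, so the test cannot decide the hypothesis. A lower neutrophil share and a change in either cell type stay open.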
